A study of Arabidopsis thaliana with 9 samples.

How the data were processed

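Messenger RNA of whole Arabidopsis thaliana seedlings was sequenced in 9 libraries of 3 groups, with 3 replicates each: the wild-type strain Col-0, a line overexpressing the microRNA gene MIR394A (MIR394A OE), and Col-0 grown with 2 µM Brz, a compound the labels do not spell out. Per the labels' protocols, seeds were kept at 4 °C for 4 days, seedlings grew at 22 °C with 16 h of light and 8 h of darkness, and RNA was taken at an age of 5 days. The labels do not say whether replicates came from separate growths or whether the overexpressor is 1 line, so the p-values measure the spread between these libraries, which may be technical in part.

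The authors deposited a single table of FPKM values (fragment counts scaled by transcript length and library depth), per the file headers. Bowtie2 and HISAT are named in the submitters' processing notes, with no role or version. The genome build, the annotation and the program that computed FPKM are not given in the sources used here, nor is whether counting used the strand, so reads of overlapping or antisense genes and of near-identical copies may be assigned to either gene. The table lists 27647 loci, of which 3316 are blank in all libraries and 24331 have values, given to 2 decimals. Of the loci, 27438 matched locus names of the TAIR10.1 reference table, which was used for names, neighbours and the length of the longest spliced transcript. No library pair was identical. All 9 value columns were used.

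FPKM values are not counts, so the tests were made on log2(FPKM + 1), and fold changes on this scale understate the change of low genes. Low FPKM values of genes with 1 annotated transcript fell on steps that fit whole reads at a depth of 21.6 to 21.8 M reads in every library, with a fitted length offset of 35 to 40 bases. Between 84.4% and 88.8% of the values used lay within 0.1 of a whole read. The libraries therefore had nearly equal depth, and counting error is similar between groups. FPKM summed to 736081 to 861647 per library.

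Genes with an FPKM of at least 1 in at least 3 libraries were tested, 17662 in all. One limma model (version 3.58.1, R 4.3.3; lmFit and eBayes with an intensity trend) was fitted to the 9 libraries with group means and 6 residual degrees of freedom, with 3 contrasts. P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. Tests covered both directions. Of 26 gene lists fixed before the data were examined, the 23 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, in one direction. List p-values were adjusted over the 23 lists.

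The genes named were chosen by a rule fixed in advance. It took, per contrast, the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change (5 and 5 for MIR394A OE against Brz) whose higher group mean was at least 5 FPKM and whose replicates did not overlap between groups. It added the 4 members of each list with the smallest p, the miR394 and brassinosteroid genes, and genes called in both comparisons with Col-0.

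Alternatives fixed in advance were limma without an intensity trend, median-ratio scaling, quantile normalization, no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 5, each replicate left out in turn, the replicate number as a block, only the 2 groups compared, stricter thresholds and library weights. Added after seeing the data were removal of a loess trend on log2 transcript length per library (span 0.5), the same with GC content, leaving out Col-0 replicate 2 with MIR394A OE replicate 3, leaving out Brz replicate 1 for the list counts, and the first residual component as a covariate. For the length correction, 132 tested genes had no transcript length and were only shifted by the library median.

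The fit was tested on simulated data for the real genes with 200 genes changed. The noise was drawn independently for each gene, and changes were planted only in genes with higher means in Col-0. The shares below therefore do not cover low genes, nor deviations that a library shares across genes, as these libraries have. For MIR394A OE against Col-0 (17662 genes), it recovered 9.1% of genes changed by 0.5 on the log2 scale, 61.2% of those changed by 1 and 97% of those changed by 2, and 5.9% of the calls were false. For Brz against Col-0 the shares were 4.5%, 56.7% and 92.5%, with 3.7% false. With a length trend imposed on the simulated Brz libraries, 2863 unchanged genes were called, and 4 after the trend was removed, while the share of the 200 changed genes recovered went from 69.5% to 51%. The imposed trend was linear in log2 length and alike in all simulated Brz libraries, so its removal worked by design. This does not show that the correction spares effects of the treatment that follow length. The miR394 site in LCR was found by matching the mature sequence of the reference to spliced transcripts, with a score that adds up mismatches.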

Results

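Transcript levels of 5-day-old seedlings were compared between untreated Col-0, Col-0 treated with Brz, and MIR394A OE, with 3 libraries per group. The title of the series puts the question as the part of miR394 in brassinosteroid signalling and hypocotyl growth. Depth was nearly equal, at 21.6 to 21.8 M reads as fitted from the FPKM steps. On a principal component analysis of the tested genes, the first component held 61.9% of the variance and separated the Brz-treated libraries, at 23.8, 64.9 and 64.5, from the others, at -30.7 to -18.2. Brz-treated replicate 1 lay between the other Brz-treated libraries and the rest. The second component, with 16.7%, placed Col-0 replicate 2 (-26.0), MIR394A OE replicate 3 (-29.0) and Brz-treated replicate 1 (-23.6) apart from the remaining libraries (3.6 to 25.6).

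Expression in the Brz-treated libraries varied with transcript length. Across 17530 genes, which are not independent replicates, the log2 fold change of Brz-treated against untreated Col-0 had a Spearman correlation of -0.67 with length. The median was 0.38 in the shortest length quintile of the genes and -0.72 in the longest. In MIR394A OE against Col-0 the correlation was -0.15. The main counts of genes and of list members in the comparisons with the Brz-treated libraries are therefore given with and without the length trend, and counts with a library left out without its removal unless said otherwise.

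**Figure D1:**
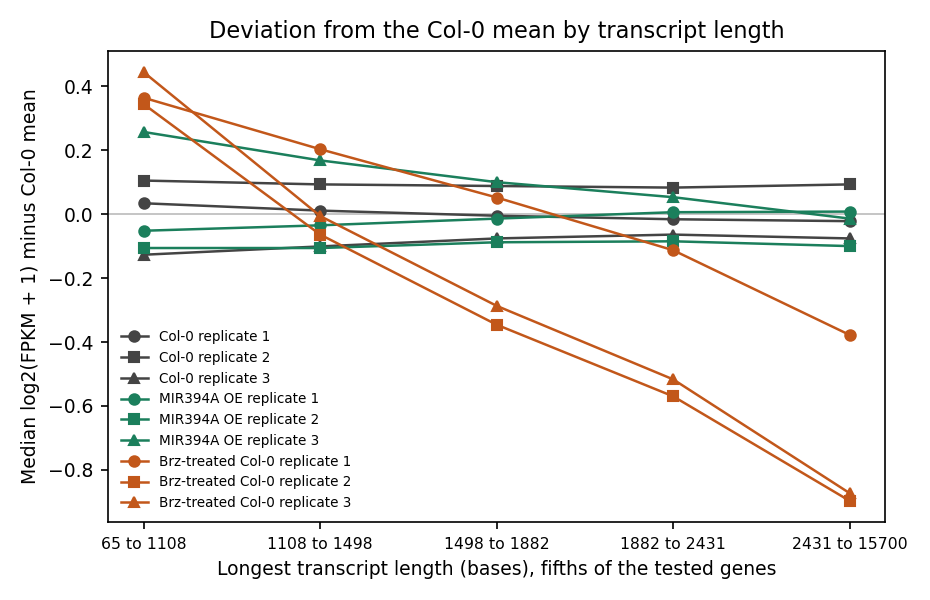
Median difference of log2(FPKM + 1) from the Col-0 mean (vertical axis) in quintiles of the tested genes by transcript length in bases (horizontal axis), with 1 line per library and marker shapes for replicates. The Brz-treated libraries run from above 0 in the shortest genes to below 0 in the longest, with a longest-quintile group median of -0.72.

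In MIR394A OE seedlings 6 genes were lower than in Col-0. QQS (AT3G30720), a gene of starch metabolism, fell from 20.9 ± 2.97 FPKM in Col-0 to 0.74 ± 0.49 (SD, n = 3), a log2 fold change of -3.69 ± 0.22 (SE, adjusted p = 8.8e-06). MRD1 (AT1G53480) fell from 16.5 ± 2.82 to 0.74 ± 0.29 FPKM (-3.33 ± 0.20, adjusted p = 8.8e-06), and AT1G75945 from 10.97 ± 3.15 to 1.37 ± 0.50 (-2.32 ± 0.23, adjusted p = 0.0017). ABCB19 (AT3G28860), an auxin transporter, fell from 23.6 ± 1.07 to 7.12 ± 1.25 FPKM (-1.61 ± 0.21, adjusted p = 0.017), and AT3G52870, which encodes a protein with a calmodulin-binding motif, from 8.69 ± 0.62 to 2.60 ± 0.56 (-1.44 ± 0.19, adjusted p = 0.017). AT5G03090 was lower, at 1.31 ± 0.92 against 7.65 ± 2.40 FPKM (-1.94 ± 0.28, adjusted p = 0.039). Its product name is similar to that of MRD1, and whether the 2 genes share reads was not tested. Its call was lost under median-ratio scaling (-1.92, adjusted p = 0.30) and with the length trend removed (-1.99, adjusted p = 0.32), with nearly the same log2 fold change. Of 17662 genes tested with limma, 6 were lower and 0 higher at an adjusted p under 0.05, with or without an intensity trend, and 401 had an unadjusted p under 0.05. Groups did not overlap in 1019 genes (5.8%), where chance gives 10%. The count was 3 without Col-0 replicate 1, 3 without Col-0 replicate 3 and 2 without Col-0 replicate 2 and MIR394A OE replicate 3 together.

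**Figure D2:**
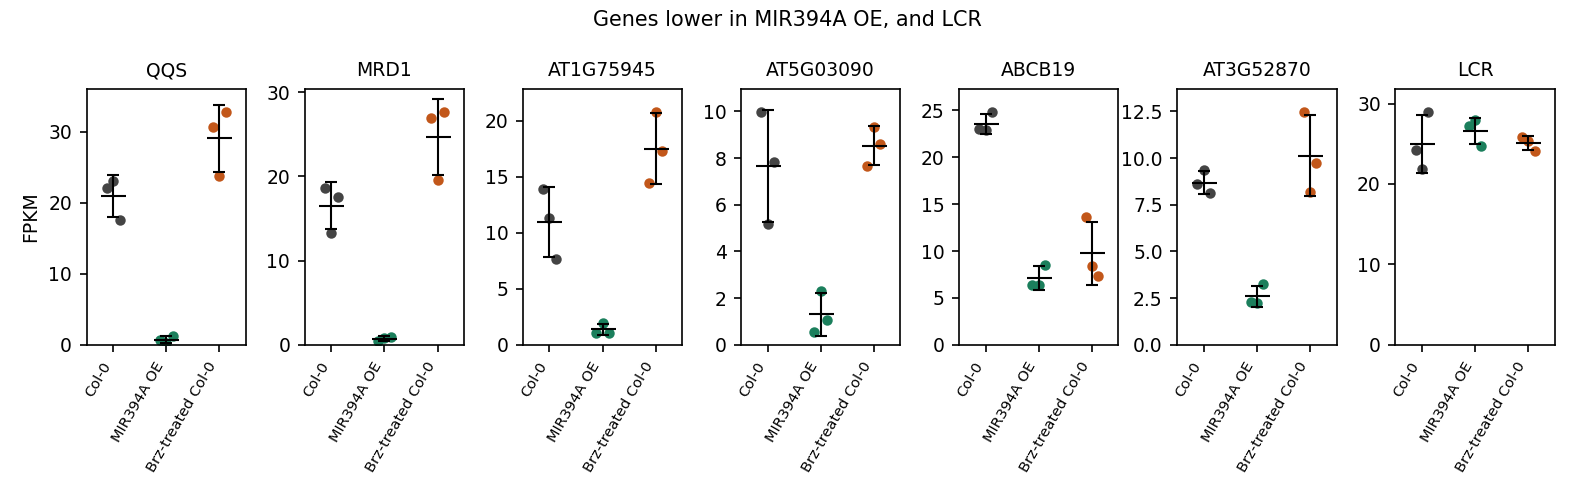
FPKM (vertical axes, from 0) of the 6 genes lower in MIR394A OE and of LCR, by group, with 1 point per library and the mean ± SD in black. The 6 genes are lower in MIR394A OE than in Col-0 in every library, while LCR lies at 26.6 ± 1.64 in MIR394A OE and 24.98 ± 3.61 in Col-0.

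LCR (AT1G27340), the F-box gene known as the target of miR394, did not differ detectably between MIR394A OE and Col-0. It measured 26.6 ± 1.64 FPKM in MIR394A OE, 24.98 ± 3.61 in Col-0 and 25.1 ± 0.90 in Brz-treated Col-0 (SD, n = 3), with a log2 fold change of 0.10 ± 0.14 (SE) in MIR394A OE. Its miR394 site, GGAGGTTGACAGAATGCCAA, was matched in TAIR10.1 on chromosome 1, from 9497605 to 9497624 on the + strand, in the coding sequence of exon 2 of 2, with a mismatch score of 1. Values of the MIR394A and MIR394B precursors were not analysed here, so the overexpression itself was not checked. Of the brassinosteroid genes, DWF4 (0.04 ± 0.23), CPD (-0.12 ± 0.14), BRI1 (0.01 ± 0.19), BIN2 (-0.09 ± 0.14), BZR1 (-0.08 ± 0.16) and BES1 (0.06 ± 0.13, log2 fold change ± SE) were not called.

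With camera, 9 of the 23 fixed gene lists were called in MIR394A OE against Col-0, and 0 were called with an estimated correlation (lowest adjusted p = 0.29) or with fry (lowest adjusted p = 0.54). A split of these libraries that mixed the 2 groups also gave 9 camera calls. Such a split keeps part of the group difference, so it is no measure of chance. The number of calls is not read as a difference between the groups. The list of SAUR genes, short auxin-induced growth genes, had the smallest camera value (adjusted p = 6.2e-15, and 0.29 as adjusted p with an estimated correlation), with a median log2 fold change of 0.45. Of its 19 members 0 were called over all genes, and 3 were called higher when adjusted over the list alone (11 with the length trend removed). SAUR20 measured 57.4 ± 8.72 against 37.7 ± 5.87 FPKM and SAUR50 55.0 ± 8.87 against 36.1 ± 0.54. Several SAUR genes are near-identical copies, so their values may share reads. The glucosinolate list, defence compounds of the cabbage family, had a median of -0.43 (camera adjusted p = 9.9e-06, and adjusted p = 0.33 with an estimated correlation). Of its 17 members 0 were called over all genes and 4 were called lower when adjusted over the list alone. CYP79F1 measured 6.15 ± 0.89 against 16.1 ± 0.82 FPKM (adjusted p = 0.16). The other camera calls, each also lost with an estimated correlation, were positive for the endodermis and suberin, expansin and XTH, and root hair lists, and negative for the salicylate and immune, flavonoid, iron deficiency and ethylene lists. MIR394A OE replicate 3 stood apart from the other MIR394A OE libraries in the direction of the call for the SAUR (median difference 0.36), glucosinolate (-0.32), endodermis and suberin (0.30) and root hair lists (0.14). It stood apart against that direction for the salicylate and immune (0.59), iron deficiency (0.64), flavonoid (0.22), expansin and XTH (-0.18) and ethylene lists (0.06). Col-0 replicate 2 stood above the other Col-0 libraries by 0.51 for the root hair, 0.46 for the endodermis and suberin and 0.28 for the SAUR list, and by -0.06 to 0.25 for the other called lists. WRKY33 of the salicylate and immune list measured 14.6 FPKM in MIR394A OE replicate 3 and at most 5.10 in the others, against 14.3 to 15.3 in Col-0. Without MIR394A OE replicate 3 the salicylate and immune and the iron deficiency lists were still called, and the calls of the glucosinolate list (adjusted p = 0.075) and the ethylene list (adjusted p = 0.30) were lost. The call of list Root_hair, MIR394A OE vs Col-0, was lost, with the sign of the test turned, without Col-0 replicate 1 (adjusted p = 0.773) and without MIR394A OE replicate 1 (adjusted p = 0.995). The list of brassinosteroid-induced growth genes was not called, with a median of -0.08, a mean of 0.00 and a positive sign of the test. Of its 14 members 0 were called over all genes, and XTH17 (0.46 ± 0.14) and PRE1 (0.57 ± 0.18) were called higher when adjusted over the list alone, but 0 with the length trend removed. That of brassinosteroid synthesis and inactivation was not called either, with a median of 0.03, a mean of -0.02 and a negative test.

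Among the genes with the largest increases in Brz-treated seedlings over untreated Col-0 were AT5G57785, of no known function (718 ± 186 against 94.5 ± 16.7 FPKM, log2 fold change 2.89 ± 0.26), the cold and abscisic acid response genes KIN1 (2.69 ± 0.52) and KIN2 (2.74 ± 0.49), which are close copies, and ICL, the isocitrate lyase of the glyoxylate cycle (log2 fold change 2.25 ± 0.40). DI21, a drought-induced gene, rose by 2.21 ± 0.22. AT1G07500 was listed at 0 in every Col-0 library and at 4.56, 6.56 and 8.36 FPKM in the Brz-treated replicates. Among the largest decreases were the cell wall protein genes LRX3 (23.7 ± 3.77 against 114 ± 44.5 FPKM, -2.16 ± 0.28) and PRP4 (329 ± 38.1 against 1422 ± 413, -2.08 ± 0.25), the nitrate transporter gene NRT1.5 (-2.11 ± 0.17) and the sucrose-phosphate synthase gene ATSPS4F (-1.98 ± 0.34). Each of these genes was also called with the length trend removed, where AT5G57785 stood at 2.84, LRX3 at -1.47 and ATSPS4F at -1.05 ± 0.32 (adjusted p = 0.041). The list of 18 cold and abscisic acid genes was not called (camera adjusted p = 0.21, and 0.073 with the length trend removed), with a median of 0.05. KIN1, KIN2 and RD26 (47.6 ± 5.52 against 22.0 ± 11.5 FPKM) rose and RD22 fell (-0.93 ± 0.13), with the same counts adjusted over the list alone, and 5 rose and 2 fell with the length trend removed. Within their groups, Col-0 replicate 2 and MIR394A OE replicate 3 stood above the other libraries by medians of 0.97 and 0.61 over this list. With these libraries left out, 7 members rose and 1 fell, and 10 rose and 1 fell with the length trend removed.

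In all, Brz-treated seedlings had 2333 genes higher and 5065 lower than untreated Col-0 (limma, adjusted p under 0.05), of which 487 and 1010 had an absolute log2 fold change of at least 1 (973 and 369 with median-ratio scaling, 233 and 278 with the length trend removed). The median over all tested genes was -0.22, and with median-ratio scaling, which set it to -0.01, the counts were 4132 higher and 3687 lower. With the length trend removed they were 2239 higher and 1976 lower, and 1339 genes were higher and 1211 lower under all 3 treatments of the values. Groups did not overlap in 50.1% of the genes, where chance gives 10%. The count was 4174 without Brz-treated replicate 2 and 4446 without Brz-treated replicate 3.

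Some genes of brassinosteroid synthesis rose and some growth genes fell. Of the 6 P450 genes of brassinosteroid synthesis, 3 were higher and 0 lower, and the same counts were found when adjusted over the list alone. They were DWF4 (9.71 ± 3.15 against 4.46 ± 0.90 FPKM, 0.95 ± 0.23, adjusted p = 0.0070), CPD (155 ± 14.98 against 110 ± 7.70, 0.48 ± 0.14, adjusted p = 0.015) and BR6OX2 (24.9 ± 8.79 against 9.02 ± 2.58, 1.35 ± 0.30, adjusted p = 0.0045). The list missed the camera threshold (adjusted p = 0.057), and passed it with median-ratio scaling (adjusted p = 0.029). With the length trend removed DWF4 stood at 1.58 and CPD at 0.79, ROT3 was called too, at 0.80, and the list reached an adjusted p of 2.6e-04, against an adjusted p of 0.18 with an estimated correlation. By fry this list was not called before removal (adjusted p = 0.14) and was called higher after it (adjusted p = 7.3e-04). BAS1, which inactivates brassinosteroids, fell from 6.16 ± 0.82 to 2.16 ± 0.67 FPKM (log2 fold change -1.20, and -0.76 with the length trend removed). Of 14 brassinosteroid-induced growth genes, 7 fell (7 adjusted over the list alone; 5 fell and 2 rose with median-ratio scaling), among them the expansin gene EXPA8 (83.3 ± 6.56 against 168 ± 13.2 FPKM), IAA19 (log2 fold change -0.98 ± 0.16) and PRE6 (-0.76 ± 0.13). The list was not called by camera (adjusted p = 0.21, and 0.27 with median-ratio scaling), but was called lower by fry (adjusted p = 0.028). With the length trend removed, a correction chosen after seeing the data, 8 fell and the list was called (camera adjusted p = 7.0e-04, and adjusted p = 0.18 with an estimated correlation). The fry value was then an adjusted p of 7.3e-04.

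**Figure D3:**
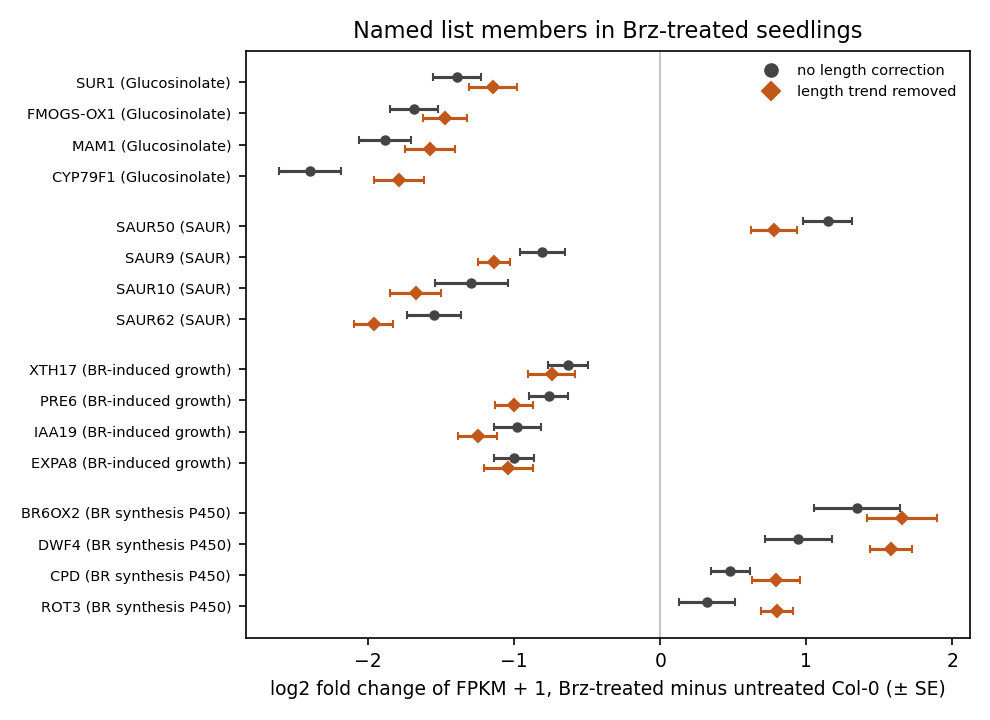
Log2 fold change ± SE of FPKM + 1, Brz-treated minus untreated Col-0 (horizontal axis), for the 4 members of 4 gene lists with the smallest p (vertical axis), without length correction (circles) and with the length trend removed (diamonds). The 16 genes have the same sign both ways, and DWF4 moves from 0.95 to 1.58.

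SAUR genes depended on the length correction. Of 19 members, 1 rose and 7 fell without it, also when adjusted over the list alone (camera adjusted p = 0.54), and 1 rose and 14 fell with it (adjusted p = 4.7e-08, and adjusted p = 0.18 with an estimated correlation). With fry the list had an adjusted p of 0.18 without the correction and 7.3e-04 with it. SAUR62 fell from 21.1 ± 5.27 to 6.41 ± 0.53 FPKM (-1.55 ± 0.18), while SAUR50 rose from 36.1 ± 0.54 to 82.2 ± 16.1 (1.15 ± 0.17). With median-ratio scaling 3 rose and 6 fell. Without Brz-treated replicate 1, 6 members were lower before and 12 after the correction.

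Of 17 glucosinolate genes 13 fell and 0 rose (13 adjusted over the list alone), and 10 fell with the length trend removed. The list was called by camera both ways (adjusted p = 4.7e-04 and 2.2e-05), with adjusted p = 0.91 and 0.18 with an estimated correlation, and by fry (adjusted p = 0.0031). CYP79F1 and MAM1, enzymes of the methionine-derived compounds, fell from 16.1 ± 0.82 to 2.33 ± 0.92 FPKM (-2.40 ± 0.21) and from 56.8 ± 4.89 to 14.8 ± 2.91 (-1.88 ± 0.18).

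The lists of brassinosteroid signalling and of cellulose synthesis genes were called by camera only without the length correction. The list medians were -0.72 and -0.96 without it. With it they were -0.29 and -0.31, against -0.007 over all tested genes. Of 14 signalling genes 11 fell, and 12 when adjusted over the list alone (camera adjusted p = 0.010, and adjusted p = 0.91 with an estimated correlation), against 4 lower and 1 higher with the trend removed (camera adjusted p = 0.11). Fry gave an adjusted p of 0.0047 before and 0.22 after removal. After removal 1 was lower and 1 higher without Brz-treated replicate 1. Without Col-0 replicate 2 and MIR394A OE replicate 3, 6 were then lower and 1 higher. The receptor gene BRI1 changed by -1.36 ± 0.19 before and -0.45 after removal, where it was not called (adjusted p = 0.13), and the kinase gene BIN2 by -0.92 ± 0.14 before and -0.59 after (adjusted p = 0.020). Of 8 cellulose genes of the primary wall 7 fell, also when adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.91 with an estimated correlation), against 3 lower and 1 higher with the trend removed (camera adjusted p = 0.13). For this list fry gave an adjusted p of 0.0050 before and 0.22 after removal. CESA1 went from -1.09 ± 0.18 to -0.20, where it was not called (adjusted p = 0.36). The 3 list calls became 6 without Col-0 replicate 2, 5 without Col-0 replicate 3 and 5 without Brz-treated replicate 3. Mixed splits of the libraries gave up to 10 camera calls, though each keeps part of the group difference. With fry 8 lists were called lower, the expansin and XTH, jasmonate and auxin lists besides the glucosinolate, growth, signalling, cellulose and iron deficiency lists. A fry call does not set a list against the other genes, and the median over all tested genes was -0.22. With the length trend removed, camera also called the expansin and XTH list lower (adjusted p = 0.018, and 0.64 with an estimated correlation). Its fry value was then an adjusted p of 0.062. Of its 14 members 7 fell and 1 rose before removal (camera adjusted p = 0.24), and 6 and 1 after it. This list shares members with the growth list, among them EXPA8.

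Of 10 iron deficiency genes 6 fell (6 adjusted over the list alone), among them BTS (-1.42 ± 0.22, and -0.49 ± 0.13 with the length trend removed) and NAS4 (-0.95 ± 0.21), and 5 with the length trend removed (camera adjusted p = 0.070 and 0.0035, with adjusted p = 0.91 and 0.41 with an estimated correlation). This list was called lower by fry both ways (adjusted p = 0.031 and 0.024). Of 27 genes of photosynthesis and chlorophyll synthesis 9 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.13), and 6 rose and 2 fell with the length trend removed (camera adjusted p = 0.43). Without Col-0 replicate 2 and MIR394A OE replicate 3, 8 rose and 7 fell, and 2 rose and 4 fell with the length trend removed. LHCB1.1 (1.14 ± 0.16) and LHCB1.2 (0.97 ± 0.14), near-identical antenna protein genes, rose, and RCA, the Rubisco activase gene, fell by 0.80 ± 0.13 on the log2 scale, a call lost with the length trend removed (adjusted p = 0.077). Median and test differed in sign for 5 lists, none of them called: brassinosteroid synthesis and inactivation (median -0.12), gibberellin (-0.12), endodermis and suberin (-0.11), flavonoid (-0.06) and light (-0.25), with positive tests.

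In the direct comparison with Brz-treated Col-0, 13 of the 19 SAUR genes were higher in MIR394A OE and 1 lower (13 and 1 adjusted over the list alone), and 16 and 0 with the trend removed (camera adjusted p = 0.0063 and 5.2e-14, with adjusted p = 0.71 and 0.16 with an estimated correlation). BR6OX2 (-1.59 ± 0.30), DWF4 (-0.91 ± 0.23, and -1.51 with the trend removed) and CPD (-0.61 ± 0.14) were lower in MIR394A OE. QQS (-4.14 ± 0.22) and MRD1 (-3.88 ± 0.20) had the largest negative values, and PRP4 (2.07 ± 0.25) and LRX3 (2.11 ± 0.28) were among the largest positive ones. In all, 4559 genes were higher and 2115 lower in MIR394A OE (limma, adjusted p under 0.05), 1746 higher and 1875 lower with the length trend removed, and 3503 higher and 3838 lower with median-ratio scaling. The count was 3959 without MIR394A OE replicate 1, 3587 without Brz-treated replicate 2 and 3816 without Brz-treated replicate 3.

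Both comparisons with Col-0 called 3 genes. ABCB19 was lower in both, at -1.23 ± 0.21 with Brz, where the call was lost with the length trend removed (-0.33, adjusted p = 0.11). MRD1 (0.55 ± 0.20) and AT1G75945 (0.65 ± 0.23) were lower in MIR394A OE and higher with Brz, and with the length trend removed both calls with Brz were lost (MRD1 0.38, adjusted p = 0.16; AT1G75945 -0.10, with its sign turned, adjusted p = 0.80). The count was 0 without Col-0 replicate 2, 0 without Col-0 replicate 3, 1 without Col-0 replicate 1 and 1 without Brz-treated replicate 3. Independent lists of these sizes would share 1.72 genes lower in both and 0.793 in opposite directions. Simulated unchanged groups with shared controls gave a median of 0, but such groups hold no changed genes, so this follows by construction. It cannot show what shared controls add to the overlap when many genes change with Brz. The log2 fold changes of the comparisons had a Pearson correlation of 0.27 and a Spearman correlation of 0.30 across genes, which are not independent replicates, and the Pearson value was 0.05 without MIR394A OE replicate 3. Unchanged groups simulated against the same controls gave a median Pearson correlation of 0.51 (95% of simulations from -0.56 to 0.91), so the observed value lay within that range. The simulated groups did not change, while many genes were called with Brz, so this range cannot decide whether the comparisons share changes. The covariance was 0.030, and 0.023 with the length trend removed, against a simulated median of 0.020 (95% of simulations from -0.01 to 0.067) and of 0.025 with independent noise, so it lay within the simulated range too. The 3 control libraries were not split between the comparisons, since 1 part would hold a single library, and part of any excess may come from sharing them.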

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

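The tests with the length trend removed, with length and GC trends removed, with the first residual component, and with Col-0 replicate 2 and MIR394A OE replicate 3 left out were chosen after seeing the data. The count of genes called in MIR394A OE against Col-0, 6 in the main test and all lower, became 3 with no filter, 3 with only the 2 groups compared, 3 at an adjusted p under 0.01, 2 with Col-0 replicate 2 and MIR394A OE replicate 3 left out, and 3 to 6 with single libraries left out. Here and below these are counts of calls, which can include other genes. Without MIR394A OE replicate 2 the calls were 4 lower and 1 higher. The LCR log2 fold change stayed between 0.01 and 0.20 with single libraries left out and was not called. The 7398 genes of Brz against Col-0 became 3867 at an adjusted p under 0.01, 1497 with an absolute log2 fold change of at least 1, 4215 with the length trend removed, 4783 with length and GC trends removed, and 4174 to 9485 with single libraries left out. The 6674 genes of MIR394A OE against Brz became 3293, 1265, 3621, 4205 and 3587 to 9012 in the same order. Stricter thresholds call fewer genes by construction. For the other changes the cause was not tested.

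The 3 genes called in both comparisons with Col-0 became 5 with median-ratio scaling, 5 with quantile normalization, 0 with no filter, 1 with a pseudocount of 0.1, 5 with a pseudocount of 5, 0 at an adjusted p under 0.01, 1 with an absolute log2 fold change of at least 1, 1 with the length trend removed, 1 with length and GC trends removed, 0 with Col-0 replicate 2 and MIR394A OE replicate 3 left out, and 0 to 3 with single libraries left out. The fold-change correlation of 0.27 was 0.13 with Col-0 replicate 2 and MIR394A OE replicate 3 left out, and 0.0523 to 0.367 with single libraries left out. The 9 lists called in MIR394A OE against Col-0 became 0 with an estimated correlation and 0 with fry. The 3 lists called in Brz against Col-0 became 5 with median-ratio scaling, 6 with quantile normalization, 6 with no filter, 5 with only the 2 groups compared, 6 with library weights, 0 with an estimated correlation, 8 with fry, 6 with the length trend removed, 6 with length and GC trends removed, 6 with Col-0 replicate 2 and MIR394A OE replicate 3 left out, and 3 to 6 with single libraries left out. The cause was not tested.

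Library weights called 908 genes in MIR394A OE against Col-0, 12332 in Brz against Col-0, 12818 in MIR394A OE against Brz and 553 in both comparisons with Col-0. In 20 simulations the residuals of whole libraries were shuffled and given random signs, with no group effect planted. The weighted fit made calls in 13, 13 and 15 of them, with up to 11494, 16087 and 9128 genes, so the weighted counts are not read as changes. The unweighted fit made calls in 1 of the 20 for each comparison, with 2801 genes for MIR394A OE against Col-0, 1394 for Brz against Col-0 and 6476 for MIR394A OE against Brz, the last close to the 6674 called in the data. A draw can place libraries with alike deviations in 1 group, so a count from a single draw does not tell how often chance reaches it.

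With the length trend removed, 55 genes of Brz against Col-0 and 35 of MIR394A OE against Brz were called in the opposite direction to their call without removal. Among the named genes that were called, signs turned with the length trend removed and with length and GC trends removed for EBF1, Brz-treated vs untreated Col-0 (0.162 and 0.196), AT1G75945, Brz-treated vs untreated Col-0 (-0.0959 and -0.194), LOX3, MIR394A OE vs Brz-treated Col-0 (-0.21 and -0.28) and FRO3, MIR394A OE vs Brz-treated Col-0 (-0.107 and -0.115). With length and GC trends removed they also turned for EBF1, MIR394A OE vs Brz-treated Col-0 (-0.00318) and GI, MIR394A OE vs Brz-treated Col-0 (-0.0106). The list Root_hair, MIR394A OE vs Col-0, had adjusted p-values from 6.9e-05 to 0.995 with single libraries left out, and turned its sign without Col-0 replicate 1 (0.773) and without MIR394A OE replicate 1 (0.995). The cause was not tested.

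The deviations of Col-0 and MIR394A OE libraries of the same replicate number had correlations of -0.23, -0.64 and -0.536. Pairs of the same number with a Brz-treated library had correlations from -0.226 to 0.153. These values show no pairing by number, but cannot exclude that such libraries were grown or processed together. With the replicate block 3 genes were called in MIR394A OE against Col-0, 5996 in Brz against Col-0, 5280 in MIR394A OE against Brz and 1 in both comparisons with Col-0, with 10 and 3 lists. At the depth of 21.6 to 21.8 M reads, genes under 1 FPKM were mostly not tested.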

Other observations

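Among the tests here, those of depth, of ribosomal and photosynthesis genes and of library-level loss for the length trend, and those of length and of a stress response for the deviating libraries, were chosen only after the result was seen. The product classes below were also chosen after seeing the data.

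These classes had counts of called genes only and no test as a set. The ribosomal class held 293 tested genes named as ribosomal proteins, without a word for an organelle in the product name. Genes for organelle ribosomal proteins whose names lack such a word may be among them. Of the 293, 187 were higher and 10 lower in Brz-treated seedlings than in untreated Col-0 (median log2 fold change 0.55). With the length trend removed, 121 were higher and 9 lower (median 0.29). Of 80 plastid-encoded genes 26 were higher and 3 lower, and 29 and 0 with the length trend removed, where these genes had no transcript length and were only shifted by the library median. Plastid-encoded genes held 2.36%, 4.16% and 4.44% of the FPKM sum in the Brz-treated libraries against 1.87% to 1.91% in Col-0 and 1.68% to 2.48% in MIR394A OE. In the same order, the slopes of the Brz-treated libraries against log2 length were -0.151, -0.388 and -0.431. Outside the Brz group, MIR394A OE replicate 3 had both the highest share, 2.48%, and the lowest slope, 0.062. The share thus cannot be told apart from the length trend. Kinesin genes, with a median transcript length of 3286 bases, had 18 of 24 lower and 1 higher without the length correction, and 1 lower and 2 higher with it. Of 41 histone genes 14 were higher and 2 lower without it, 7 and 3 with it, and 29 and 1 with median-ratio scaling.

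The length trend in the Brz-treated libraries was weighed first. The fitted length offset of these libraries differed from the others by 1.67 bases and the depth by -0.15%, which argues against a different depth or effective length in the FPKM calculation. Without 468 ribosomal, photosynthesis and chloroplast genes the Spearman correlation with length was -0.662, and after removal of a GC trend it was -0.609, so neither accounts for it. Slopes differed between libraries of a group, from -0.43 to -0.15 with Brz and over a range of 0.137 outside it, so a loss of reads from long transcripts in single libraries may contribute. It cannot be told apart from an effect of the treatment, because all Brz-treated libraries had lower slopes than all others, and the biological explanation stays open.

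The 6 genes lower in MIR394A OE were weighed next. The number of these genes with a miR394 site of a mismatch score of at most 4 was 0 (direct miR394 target sites; their best scores were 6 to 8.5, against 1 for LCR). The median log2 fold change of their nearest tested neighbours was 0.0375, which argues against a regional change as the cause for the 6 as a set, but next to MRD1 the value was 0.079 on one side and -0.555 on the other (AT1G53490, adjusted p = 1), so at that locus it stays open. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes, the real one with 6 against at most 2 in the others, and 10 splits are too few for a share under 0.05. A difference in the genetic or epigenetic background of the line was not tested and stays open.

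Col-0 replicate 2 and MIR394A OE replicate 3 deviated from their groups together, with a correlation of their deviations of 0.55. A swap of their labels is argued against by 100% of the genes called without them placing both with their labelled group, though these were only 2 genes, QQS and MRD1. The length slope of Col-0 replicate 2 differed by -0.01 from the mean of the other Col-0 libraries, which argues against the length trend as the cause in both. The slope of MIR394A OE replicate 3 differed by -0.13 from the mean of the other MIR394A OE libraries, so in this library alone it stays open. The cold and drought list was higher in both libraries, with a lower median difference of 0.611, so a stress or dehydration response is a candidate explanation. It was found in these data and cannot be upheld by them.

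As a set, 59 tested genes with a match to miR394 of a score of at most 4 had a median log2 fold change of -0.0544 in MIR394A OE (quartiles -0.11 and 0.06), so a fall of these transcripts as a set was not seen. The score weights all positions alike and was not compared with shuffled sequences. Many of these genes may match by chance, so the median cannot decide whether true targets fell. The log2 fold changes of the 17 glucosinolate genes in the 2 comparisons with Col-0 had a Spearman correlation of 0.365, which leaves open whether the same members moved in both, since both subtract the same Col-0 libraries.

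For the other counts, 10 splits of 6 libraries are likewise too few for a share under 0.05. The real split gave 7398 genes for Brz against Col-0 and at most 1 in the others, and 6674 genes for MIR394A OE against Brz and at most 1 in the others, so 1 split reached each count. The other splits mix the 2 groups, so a large difference between the groups adds to their spread and few calls follow. The gap between these counts is therefore no measure of chance. For the gene lists of MIR394A OE against Col-0, 2 splits called as many as the real 9, with at most 9 in the others. For those of Brz against Col-0, 8 splits called at least as many as the real 3, the real one included, with at most 10 in the others. Camera at the preset correlation thus called as many lists in some mixed groups. Each mixed split keeps part of the group difference, so these list counts are no measure of chance either. The numbers of lists called are not read as differences between the groups.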
